A study of Mus musculus with 4 samples.

How the data were processed

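Small RNA was measured in 4 libraries of flow-sorted, Tbx18-lineage stroma cells from the region of the wolffian duct of mouse embryos, all of 1 genotype and 1 stage. Per the labels' protocols, cells were sorted into a lysis reagent, total RNA was taken with a micro-scale column kit that keeps small RNA, and libraries were made with a small RNA kit and sequenced on a NextSeq as single reads of 75 bp. The deposited values are TPM, reads per gene divided by gene length and scaled to a fixed total over all genes, in a table with 1 row per Entrez gene and 1 column per library. Per the submitters' processing notes, the genome build was mm10 (GRCm38) and limma was used, with no version given. The aligner, the counter, the annotation and the treatment of reads that fit several places are not given in the sources used here. TPM values in this table sum to 4.94%, 7.22%, 7.11% and 2.33% in libraries 1 to 4, as shares of the total that TPM is scaled to, so the scaling included genes not used here, and a level in TPM moves with the share of the library that such genes took. Of this table's total, miRNA genes made up 86.0%, 90.7%, 86.8% and 70.3%.

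The values were examined for the reads behind them. For every nonzero miRNA gene, TPM times the RefSeq gene length was a whole multiple of 1 constant per library, for 100% of values within a tolerance of 0.01, which gave the reads per miRNA gene. Those reads were used for depth and for alternatives, and no count model was fitted. Dividing by hairpin length, as TPM does, makes a short hairpin look more abundant than a long hairpin with the same number of reads. Small RNA libraries also carry ligation and amplification preferences that differ between miRNAs, so levels of different miRNAs within a library are relative. No source used here mentions molecular identifiers, so counting limits cover counting error only.

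Rows were joined by gene ID to NCBI RefSeq genes of GRCm38.p6, the build named in the notes, and 2541 of 2976 rows matched. The 435 unmatched rows had a highest mean of 2.97 TPM and were kept without names. Host genes, strand and hairpin sequences came from GENCODE vM21 at the same coordinates. The rows are precursor genes and not mature arms. A planned comparison of the 5p and 3p arms therefore could not be run, and plans for the higher arm or the sum of arms were adapted to gene copies, using the copy with the highest mean TPM or the sum of copies. Copies of a miRNA gene can share the mature sequence, so the split between copies is uncertain. Of 22 miRNA names with at least 2 copies and a summed mean of at least 10 TPM, 13 had over 90% of it on 1 copy. Levels listed as 0 may be limited by counting where rows overlap, and antisense genes are likewise uncertain because the counting's use of strand is not given in the sources used here.

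The 36 groups of miRNAs and the rule for named genes were fixed before the data were examined. The rule takes the 20 rows with the highest mean TPM, 2 to 4 members of each group with the highest mean, the highest and lowest member of each cluster, and the 5 largest and 5 smallest coefficients of variation among rows with a mean of at least 100 TPM. A few other members are named where a count or a value of 0 refers to them. A miRNA was called detected at 1 TPM or more in all 4 libraries. Group levels are sums over members and copies. Group percentiles used 10000 random groups with a fixed seed. Pairs of groups were compared by an exact two-sided sign-flip permutation test of log2 ratios with a pseudocount of 1 TPM. Cluster members were compared by limma with an intercept only, on log2(TPM + 1) centred within group and library, for members with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment over 37 members. A first run had left the Hox-cluster group out of this step, and the values given follow the rule as it was fixed. Every log2 value depends on the pseudocount, which understates differences of low genes. On 100 simulated data sets with the same 37 members, this step called 1.47% of members with no shift. It called 93.2% of those shifted by under 1.25 log2 units and 99.6% of those shifted by 1.25 or more. Only every second group was left without a shift. Mir19a, with the largest SD at 1.08, was not in such a group, so 1.47% does not cover the noisiest members. Most shifts under 1.25 were not far below it, so 93.2% is not the rate for small shifts. Unusual libraries were sought with Dixon's test at its 95% critical value of 0.829 for 4 values.

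Alternatives covered the pseudocount, filters on low values, rescaling, the treatment of copies, the background of the percentiles, and leaving out each library in turn. With 1 group there was no comparison between groups and no pairing. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.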

Results

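The series profiled the small RNAs of Tbx18-expressing stroma around the wolffian duct, the epithelial tube from which the ureteric bud grows, in CD1 mouse embryos at stage E10.5. Cells carried Tbx18-Cre and a CAG-tdTomato reporter, which marks with a red fluorescent protein the cells in which the Tbx18 promoter has driven Cre and their descendants, and were collected by flow sorting. There were 4 libraries and 1 group, so the data hold levels within this cell population and no comparison between conditions. The labels do not say whether the 4 libraries came from separate embryos or pools, so every spread and p-value measures only the difference between these libraries, which may be technical. The table gave TPM (length-scaled transcript abundance) for 2976 non-coding and other genes, of which 643 were miRNA precursor genes. Reads assigned to miRNA genes, recovered from the TPM values, numbered 883201, 1087240, 978210 and 146255 in libraries 1 to 4, so library 4 was the shallowest and the deepest had 7.43 times as many. A count of 0 allowed a level of up to 0.147, 0.182, 0.196 and 0.348 TPM in libraries 1 to 4 for a hairpin of 80 nt, taking 3 reads as the limit. These limits cover counting error only.

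By mean TPM, the miRNA pool was led by miRNAs encoded in Hox clusters and by the miR-99/miR-100/miR-125 group. Mir10b was the most abundant row at 6974 ± 5258 TPM (SD, n = 4), and its paralog Mir10a reached 3929 ± 2589 TPM (SD, n = 4). The Mir10b hairpin is shorter, at 68 against 110 nt, which raises its TPM for the same reads. In recovered reads Mir10a was above Mir10b in library 1, at 62174 against 45129, and below it in libraries 2, 3 and 4. Mir10b (gene ID 387144) lies on chromosome 2 at 74726070 to 74726137 of GRCm38, plus strand, within an intron of Hoxd3 and Hoxd4, and its hairpin reads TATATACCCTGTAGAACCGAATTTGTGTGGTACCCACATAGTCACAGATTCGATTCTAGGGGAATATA. Mir10a (gene ID 723893) lies on chromosome 11 at 96317165 to 96317274, plus strand, outside annotated genes, with the hairpin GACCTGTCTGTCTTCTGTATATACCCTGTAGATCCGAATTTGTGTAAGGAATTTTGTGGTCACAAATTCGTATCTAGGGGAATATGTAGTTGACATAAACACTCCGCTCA. Other abundant miRNAs, in order of their mean TPM, were Mir99a at 2615 ± 1817 TPM, Mir99b at 2174 ± 1441 TPM, Mir26a-2 at 1575 ± 925 TPM, Mir541 at 1549 ± 674 TPM and Mir148a at 1281 ± 597 TPM. By mean share of a library's summed TPM in this table, Mir541 at 2.97% was above Mir26a-2 at 2.75%. In library 4, Mir541 at 735 TPM was above Mir99b at 483 and Mir99a at 394 TPM. Mir99a lies on chromosome 16 at 77598936 to 77599000 in an intron of Mir99ahg. Mir99b lies on chromosome 17 at 17830188 to 17830257 in an intron of Spaca6. Mir26a-2 overlaps an exon of Ctdsp2 on chromosome 10 at 126995530 to 126995613, and Mir541 lies in an intron of Mirg on chromosome 12 at 109742409 to 109742498. The remaining miRNA genes among the 20 highest rows were Mir125a at 1148 TPM, Mir92-2 at 1080, Mir25 at 837, Mir5099 at 834, Mir9-3 at 830, Mir335 at 803, Mir199a-1 at 764, Mir100 at 752, Mir409 at 668, Mir125b-1 at 663 and Mir615 at 652 TPM. The mean of Mir9-3 was 153 TPM without library 3, and that of Mir125b-1 was 406 TPM without library 1. Of the 18 miRNA genes among these 20 rows, 9 lay in an intron, 5 overlapped an exon and 4 were intergenic in the annotation used. The other 2 rows were Gas5, a host gene of small nucleolar RNAs, at 5341 ± 1218 TPM, and Rny1, a Y RNA, at 1237 ± 379 TPM (SD, n = 4).

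**Figure D1:**
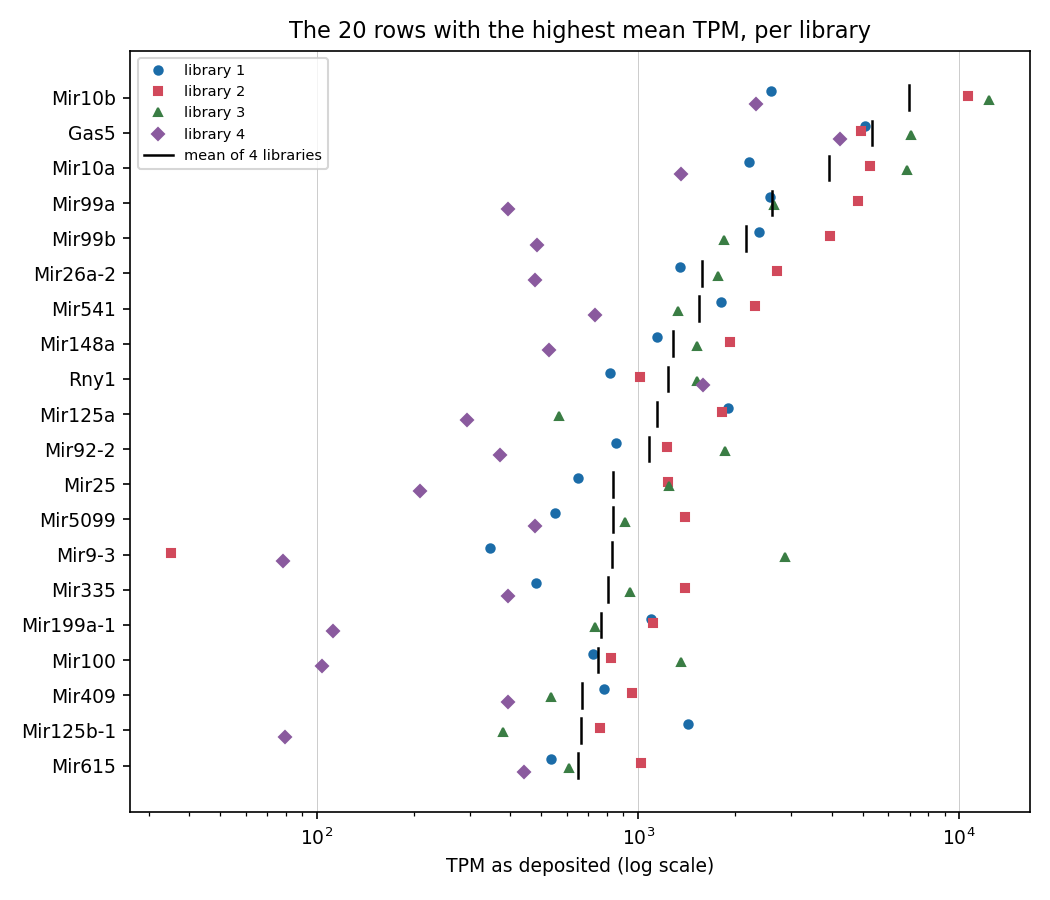
Level of each of the 20 rows with the highest mean in each of the 4 libraries, in TPM on a log axis; each marker is a library and the black line is the mean of 4. Mir10b has the highest mean, 6974 TPM, library 4 is the lowest library for most miRNA rows, and Mir9-3 spans from 35.2 to 2861 TPM.

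The pool was concentrated in few genes. Shares here are of a library's summed TPM in this table, itself 2.33% to 7.22% of the total that TPM is scaled to. With rows ranked by their mean over the libraries, the highest row, Mir10b, took 11.8% ± 5.34 of that sum (SD, n = 4). The 10 highest rows took 51.2% ± 4.71 and the 20 highest 65.3% ± 4.44 (SD, n = 4). Ranked within each library, the highest row took 15.1% ± 3.57 (SD, n = 4; a ranking added after the data were seen), and it was Gas5 in libraries 1 and 4 and Mir10b in libraries 2 and 3. Ranked in the same way, 62.3 ± 4.65 rows made up 90% of a library's sum in this table. Of the 643 miRNA genes, 213 reached at least 1 TPM in all 4 libraries, and 250, 261, 282 and 234 did so in libraries 1 to 4 taken alone. Another 203 were listed at 0 in all libraries. Several of these overlap another row of the table, and a 0 there is a listed value, not evidence that the miRNA was absent.

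Groups of miRNAs were fixed before the data were examined, as families, loci and markers of cell types, and 32 of the 36 groups summed to at least 1 TPM in every library. Hox-cluster miRNAs summed to 12371 ± 8199 TPM, or 25.8% ± 7.89 of the miRNA total (SD, n = 4), with all 5 members detected in all libraries. Besides Mir10b and Mir10a this group held Mir615, in an intron of Hoxc5, and miR-196a at 549 ± 257 TPM summed over its copies. The miR-99/miR-100/miR-125 group summed to 7369 ± 4586 TPM (14.8% ± 6.15), with all 5 members detected. The maternally expressed Dlk1-Dio3 imprinted locus summed to 6019 ± 2456 TPM (14.2% ± 4.28), led by Mir541, Mir409 at 668 ± 253, Mir543 at 549 ± 244 and Mir379 at 535 ± 321 TPM (SD, n = 4). Of the 45 Dlk1-Dio3 members with a row, 34 were detected in all libraries and 8 were listed at 0, of which 6 overlapped another row. As shares of the miRNA total in libraries 1 to 4, the Hox-cluster group took 14.8%, 27.5%, 33.6% and 27.1%, the miR-99/miR-100/miR-125 group 21.3%, 18.7%, 11.1% and 8.27%, and the Dlk1-Dio3 group 16.6%, 13.3%, 8.57% and 18.3%. In library 1 both other groups were therefore above the Hox-cluster group, and in library 4 Dlk1-Dio3 was above miR-99/miR-100/miR-125. In 9 groups a member listed at 0 overlapped another row, and their sums may be understated. The other imprinted group, H19/Igf2, summed to 58.2 ± 28.5 TPM, all from Mir483, and Mir675, which overlaps another row, was listed at 0. Random groups of equal size were drawn from 408 miRNA names, 10000 times per group, to place each group's median level. The miR-99/miR-100/miR-125 group lay at the 100th percentile of these, the Hox-cluster group at 99.98 and the Dlk1-Dio3 group at 99.84, and 9 groups in all lay at or above 97.5. These percentiles describe these libraries and are not tests.

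**Figure D2:**
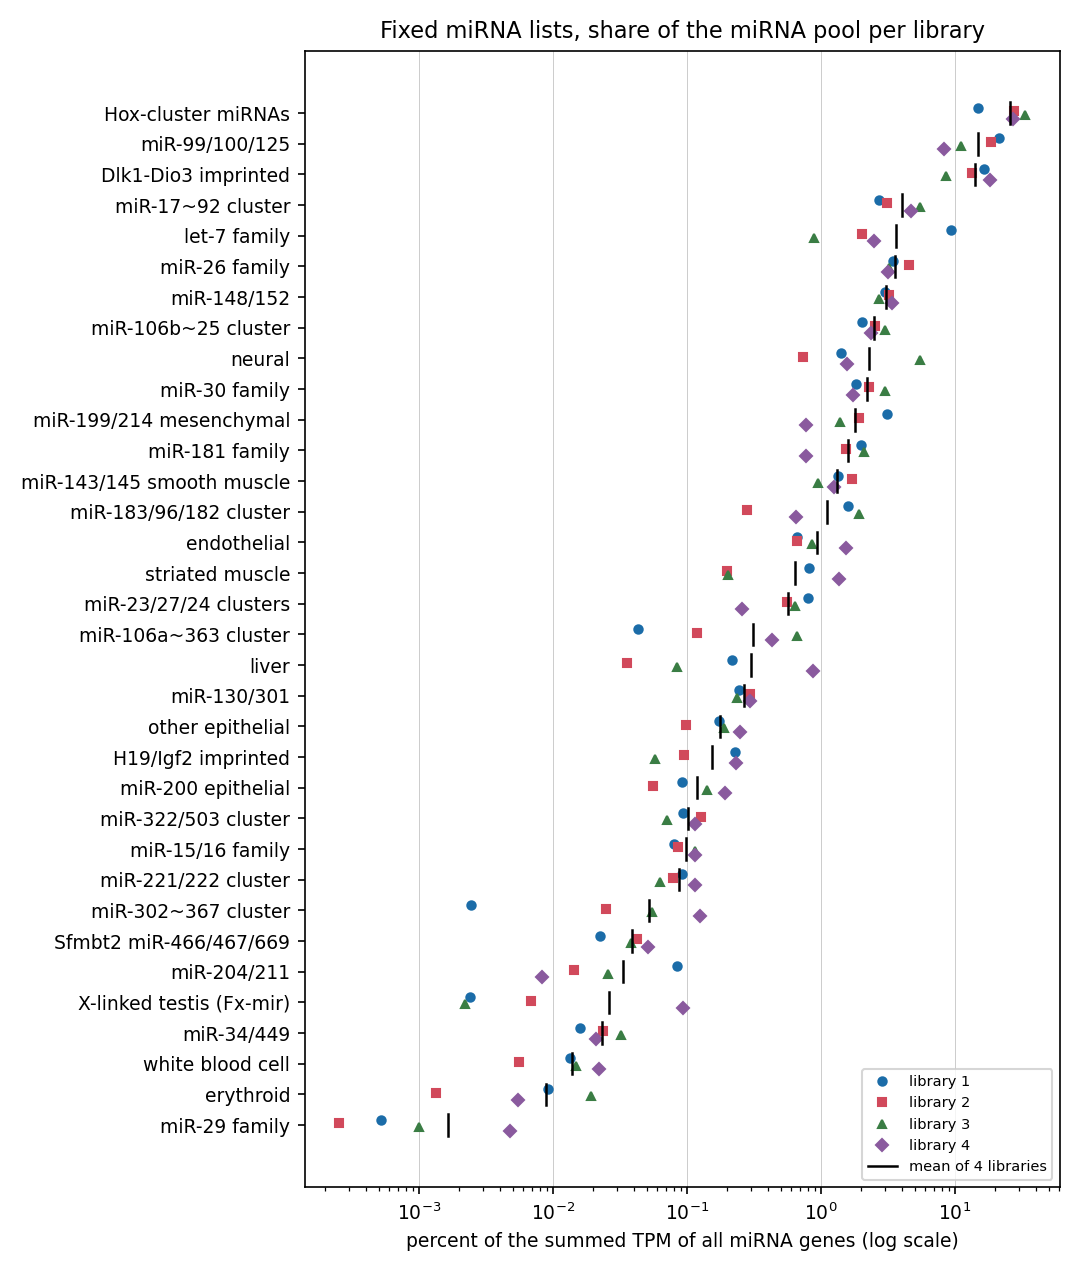
Share of the summed TPM of all miRNA genes taken by each fixed group of miRNAs, in percent on a log axis; each marker is a library and the black line is the mean of 4. Hox-cluster miRNAs average 25.8%, while the erythroid and white blood cell groups average 0.0088% and 0.0140%; the miR-290/miR-295 and miR-21 groups are not drawn.

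Among families expressed in many tissues, the miR-26 family summed to 1728 ± 1017 TPM, let-7, a family known for developmental timing, to 1552 ± 1640 TPM, miR-148/miR-152 to 1400 ± 659 TPM and miR-30, studied in kidney development, to 1101 ± 700 TPM (SD, n = 4). Within let-7 the highest members were let-7c at 497 ± 469, let-7a at 341 ± 378 and let-7f at 195 ± 243 TPM, and in miR-30 they were Mir30d at 416 ± 236 and miR-30c at 313 ± 210 TPM. Let-7 was uneven between libraries, at 3938, 1322, 543 and 407 TPM in libraries 1 to 4, and without library 1 its mean was 757 TPM, with let-7c at 281, let-7a at 153 and let-7f at 75.4 TPM. The miR-181 family summed to 815 ± 494 TPM, miR-130/miR-301 to 123 ± 61.7 TPM with Mir130b highest at 88.3, miR-15/miR-16 to 44.9 ± 23.1 TPM and miR-204/miR-211 to 15.7 ± 14.7 TPM, most of it Mir204 at 14.0 TPM (SD, n = 4). Without library 1 the miR-204/miR-211 mean was 8.92 TPM and that of Mir204 was 8.69 TPM. The miR-34/miR-449 group, linked to p53 and multiciliated cells, summed to 11.3 ± 7.55 TPM, with Mir34c at 7.93 TPM. The miR-29 family, regulators of extracellular matrix genes, had a listed sum close to the limit of detection, at 0.448 ± 0.302 TPM (SD, n = 4). Mir29c, which overlaps another row, was listed at 0, so this sum may be understated. Mir21a was listed at 0 in all 4 libraries.

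Clusters related to miR-17/miR-92, a polycistron known for its role in proliferation, were present at different levels. The miR-17/miR-92 group summed to 1833 ± 1155 TPM, miR-106b/miR-25 to 1191 ± 689 TPM and the X-linked miR-106a/miR-363 to 144 ± 178 TPM (SD, n = 4), or 55.4 TPM without library 3. Most of the miR-17/miR-92 sum was miR-92a, whose reads were all listed under Mir92-2, the copy at the miR-106a/miR-363 locus on chromosome X (52741838 to 52741928), while Mir92-1 was listed at 0. The copies share their mature sequence, so the locus of origin is uncertain. With Mir92-2 and Mir19b-2, the copies numbered for the X-linked locus, counted in the miR-106a/miR-363 group instead, an alternative chosen after the data were seen, miR-17/miR-92 summed to 745 ± 539.8 TPM and miR-106a/miR-363 to 1232 ± 791 TPM (SD, n = 4). Pluripotency clusters were low, with miR-302/miR-367 at 17.9 ± 13.5 TPM, or 1.04, 16.1, 33.7 and 20.6 TPM in libraries 1 to 4, led by Mir302b at 10.4 ± 7.48 TPM. The miR-290/miR-295 cluster of embryonic stem cells and germ cells gave 0.126 TPM in library 3 and 0 in the others, but 6 of its 7 members with a row were listed at 0 and all 6 overlapped another row. The X-linked testis group summed to 5.53 ± 6.66 TPM, led by Mir881 at 1.24 and Mir871 at 1.15 TPM, at 1.02, 4.51, 1.35 and 15.2 TPM in libraries 1 to 4, with a mean of 2.30 TPM without library 4, where Mir881 averaged 0.386 and Mir871 0.368 TPM. The repeat-rich Sfmbt2 group summed to 17.3 ± 9.83 TPM, with miR-467a at 11.5 TPM.

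Mesenchymal and smooth muscle miRNAs were at higher levels than the epithelial miR-200 family. The miR-199/miR-214 group, known from mesenchymal stroma, summed to 891 ± 550 TPM, with miR-199a at 764 ± 468 and Mir199b at 127 ± 89.9 TPM. The third member, Mir214, and the Mir199a-2 copy lie within Dnm3os and were listed at 0, so the sum may be understated to an unknown degree. Reads of Mir199a-2 may instead be listed under Mir199a-1, and would then be in the sum. Smooth muscle miR-143/miR-145 summed to 619 ± 376 TPM, almost all of it Mir143 at 593 ± 365 TPM. The miR-200 family, typical of epithelia such as the wolffian duct, summed to 48.3 ± 25.8 TPM, led by Mir200b at 27.1 ± 12.0 and Mir200c at 12.4 ± 9.02 TPM. Other epithelial miRNAs summed to 73.8 ± 31.6 TPM, led by Mir205 at 32.0 ± 28.2 and Mir192 at 19.3 ± 10.1 TPM (SD, n = 4). Without library 3 the mean of Mir205 was 19.03 TPM and that of Mir200c 7.997 TPM.

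Markers of other cell types that a sort could carry were present at unequal levels. Endothelial Mir126a reached 374 ± 131 TPM (SD, n = 4), and it was the only gene of its group with a row. Striated muscle miRNAs summed to 206 ± 103 TPM, most of it Mir206 at 191 ± 103 TPM, and Mir122 of liver reached 77.6 ± 52.1 TPM. Blood cell groups had low listed sums, the erythroid group at 4.38 ± 5.19 TPM with Mir451a at 4.14 and the white blood cell group at 5.54 ± 2.62 TPM with Mir155 at 3.43 TPM (SD, n = 4). Mir486 and Mir223, which overlap other rows, were listed at 0, so both sums may be understated. Neural miRNAs summed to 1178 ± 1466 TPM, at 601, 484, 3367 and 258 TPM in libraries 1 to 4. Without library 3 the mean was 448 TPM for the neural group and 1.89 TPM for the erythroid group, with miR-9 at 154, miR-219a at 7.15 and Mir451a at 1.81 TPM. Mir9-3 supplied most of the library 3 sum, with miR-9 at 835 ± 1370, miR-128 at 284 ± 119 and miR-219a at 53.3 ± 92.5 TPM (SD, n = 4). The miR-183/miR-96/miR-182 cluster of sensory organs summed to 540 ± 503.1 TPM and was likewise highest in library 3, at 1191 TPM, with a mean of 323 TPM without it.

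Fixed pairs of groups were compared within each library as the log2 ratio of summed TPM plus 1. The miR-199/miR-214 group exceeded miR-200 by a mean of 3.85 log2 units (1.99 to 5.08 over 4 libraries). It exceeded the erythroid group by 7.40 ± 1.63 and the white blood cell group by 6.73 ± 1.47, each in 4 of 4 libraries, with Mir214, Mir486 and Mir223 all at 0 in these sums. Against liver the ratio was 3.34 ± 2.48 and against striated muscle 1.79 ± 1.82, both higher in 3 of 4 libraries. It was not set apart from endothelial Mir126a (0.87 ± 1.38, 3 of 4), from miR-143/miR-145 (0.32 ± 0.79, 3 of 4) or from the neural group (-0.12 ± 1.64, 2 of 4). The neural ratio turned to 0.50 without library 3 and to 0.18 without library 4, and was -0.54 without library 1 and -0.62 without library 2. The miR-143/miR-145 ratio was 0.01 without library 1 and 0.64 without library 4, and the Mir126a ratio was 0.42 without library 1. Without library 4 the ratios to liver, striated muscle and Mir126a were 4.51, 2.66 and 1.49. With the median over members in place of the sum, the ratio to miR-143/miR-145 was -0.27, to endothelial Mir126a -1.99, to liver 0.48, to striated muscle 5.43 and to the neural group 3.78. From recovered reads not divided by hairpin length, the ratio to miR-143/miR-145 was 0.57 and to the neural group -0.21.

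Among developmental groups, let-7 exceeded miR-302/miR-367 by 6.35 ± 3.21 log2 units and lay below the miR-99/miR-100/miR-125 group, with a ratio of -2.45 ± 1.17, in 4 of 4 libraries. Without library 1 the first of these ratios was 4.83. The miR-17/miR-92 group exceeded miR-106b/miR-25 by 0.64 ± 0.34 and miR-106a/miR-363 by 4.27 ± 1.31, the former reversing to -0.44 when the median over members was used. Both reversed with Mir92-2 and Mir19b-2 counted in the miR-106a/miR-363 group, to -0.72 ± 0.70 (lower in 3 of 4 libraries) and -0.77 ± 0.57 (lower in 4 of 4), so both directions depend on where these copies are counted. Mir10a lay below Mir10b, with a ratio of -0.72 ± 0.34, in 4 of 4 libraries, but the ratio was -0.02 ± 0.34 from recovered reads not divided by hairpin length. Dlk1-Dio3 exceeded H19/Igf2 by 6.68 ± 0.54 (SD, n = 4), or by 1.31 with the median over members. The H19/Igf2 sum is Mir483 alone, since Mir675, which overlaps another row, was listed at 0, and both values depend on that 0. The miR-30 family exceeded miR-204/miR-211 by 6.32 ± 1.28 (SD, n = 4). The ratio of miR-302/miR-367 to miR-290/miR-295 was 3.63 ± 1.77, but the second group was at 0 in 3 libraries, so this value depends on the pseudocount, at 6.44 with 0.1 and 1.31 with 10, and was 1.68 with the median over members. In all, 16 ratios were computed and 11 had the same sign in all 4 libraries. By an exact two-sided sign-flip permutation test, those 11 gave p = 0.13 each, the smallest that 4 libraries allow, with a Benjamini-Hochberg adjusted p of 0.182. No ratio could therefore pass a threshold of 0.05 in this test.

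Members of the same group differed in level within a library. Each member's log2(TPM + 1) was set against the mean of its group's members in the same library. At an adjusted p under 0.05, limma called 34 of 37 members in 10 groups, 17 above and 17 below that mean. For its p-values, limma pools the spread of all 37 members, which share the same 4 libraries. These p-values are therefore far smaller than 4 libraries could give a member alone, and their size does not measure the evidence. In the miR-17/miR-92 group, Mir92-2, whose listed copy lies at the miR-106a/miR-363 locus, lay 3.21 ± 0.46 above (SD, n = 4; adjusted p = 6.14e-22, limma) and Mir19b-2 at -3.77 ± 0.26 (adjusted p = 1.44e-25), in all 4 libraries. Both are numbered copies of the X-linked locus, so this is not a comparison within 1 transcript. In miR-183/miR-96/miR-182, Mir183 lay at 1.61 ± 0.12 and Mir96 at -2.68 ± 0.34. The extremes of miR-106a/miR-363 were Mir363 at 2.04 ± 0.27 and Mir106a at -1.70 ± 0.33, and those of miR-106b/miR-25 were Mir25 at 1.42 ± 0.41 and Mir106b at -0.95 ± 0.14. Among the Hox-cluster miRNAs, which lie at separate loci, Mir10b stood at 2.36 ± 0.61 and Mir196b at -2.08 ± 0.19. From recovered reads not divided by hairpin length, Mir10b was at 2.01 and Mir10a at 1.98. In the paired miR-23/miR-27/miR-24 clusters Mir27b stood at 1.74 ± 0.50 and Mir27a at -1.27 ± 0.58, with the group sum at 285 ± 163 TPM and miR-24 listed at 0. Smaller spreads were seen for Mir222 and Mir221 (0.56 ± 0.33 and -0.56 ± 0.33, in a group of 37.0 ± 13.4 TPM), and for Mir302b and Mir302d (0.80 ± 0.39 and -0.58 ± 0.20). Mir450-1 and Mir542 of the miR-322/miR-503 cluster stood at 0.66 ± 0.24 and -0.62 ± 0.16, in a group that summed to 46.6 ± 27.1 TPM with Mir322, Mir503 and Mir351 listed at 0. In the Sfmbt2 group Mir467a-9 stood at 1.53 ± 0.48 and Mir669a-12 at -0.62 ± 0.17. Without library 2 the calls of Mir221 and Mir222 were lost, and Mir302d turned to 0.18 and Mir669a-12 went to -0.12 when members with any mean above 0 were included, neither of them called, while Mir302b was at 1.57. With a pseudocount of 10, Mir302d at -0.23 and Mir669a-12 at -0.22 were not called. Mir467a-9 was then at 0.59, Mir363 at 1.29, Mir106a at -0.94, Mir222 and Mir221 at 0.34 and -0.34, Mir302b at 0.36, Mir450-1 at 0.40 and Mir542 at -0.35, each still called. Mir302d was at -0.99 with a pseudocount of 0.1, and Mir669a-12 at -0.35 with the sum of gene copies. At a mean of at least 10 TPM, 21 of 26 members were called, Mir363 was at 0.66 and Mir450-1, at 0.36, was not called. Under that filter Mir20b went from 0.72 to -0.66 and was called on the opposite side, and with a pseudocount of 10 it was at 0.34 and not called. Values within a group sum to 0, so its members are not independent. Mir19a was called at 0.55 ± 1.08 (adjusted p = 0.0199, limma) although it was positive in 2 of 4 libraries only, and its call was lost without library 3, without library 4, with the sum of gene copies (adjusted p = 0.1998, limma), with a pseudocount of 10 and at a mean of at least 10 TPM, where it was at -0.21.

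**Figure D3:**
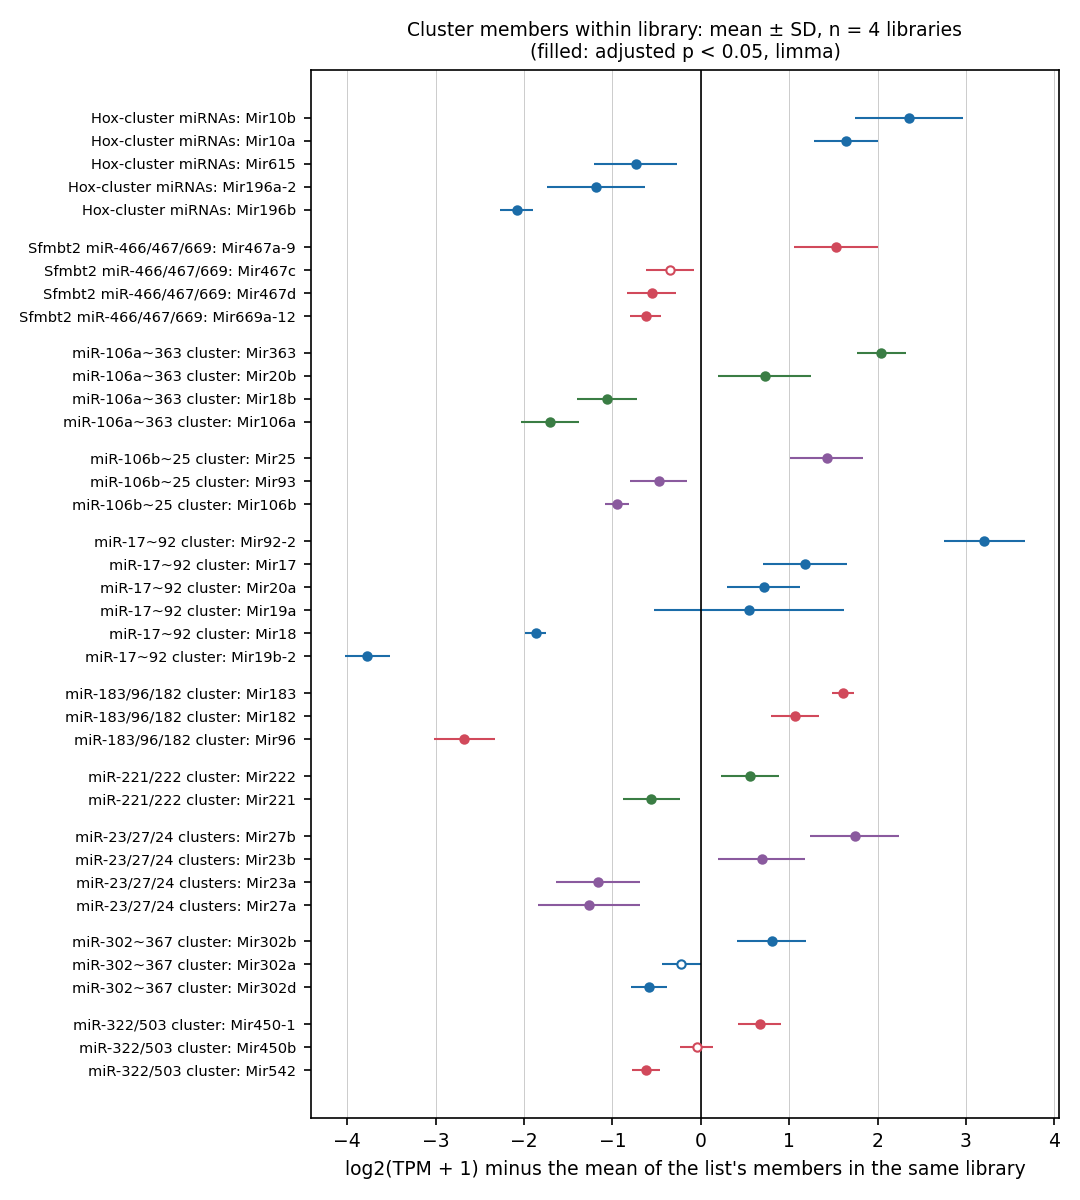
Deviation of each cluster member from its group's mean in the same library, in log2(TPM + 1) units; points are means of 4 libraries, bars are 1 SD and filled points have an adjusted p under 0.05 by limma. Mir92-2 at 3.21 and Mir19b-2 at -3.77 are the extremes, and Mir302a, Mir450b and Mir467c are open.

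Libraries varied in how much of the total was miRNA and in which miRNAs they held. Across 294 rows with a mean of at least 1 TPM, the 6 pairs of libraries had Pearson's r from 0.872 to 0.947 and Spearman's rho from 0.849 to 0.942 on log2(TPM + 1). These are correlations across genes, which are not independent replicates. Their counts differed far beyond sampling noise, with a chi-square per degree of freedom of at least 181.9 for each pair, so no libraries were merged. The median coefficient of variation of rows with a mean of at least 10 TPM was 58.5%, 38.8% after each library was rescaled to its miRNA total, and 35.6% without library 4. Among rows with a mean of at least 100 TPM it was largest for Mir9-3 at 164%, Mir92b at 129%, Mirlet7f-2 at 127%, Mirlet7a-2 at 122% and Mirlet7g at 121%. That of Mir92b was 22.0% without library 3, and those of Mirlet7f-2, Mirlet7a-2 and Mirlet7g were 69.8%, 64.1% and 74.2% without library 1. It was smallest for Gas5 at 22.8%, A230103J11Rik at 23.5%, Rny3 at 27.4%, Rmrp at 27.6% and Rny1 at 30.7%. None of these last 5 is a miRNA gene, and rescaling to the miRNA total raised them to 56.4%, 43.8%, 94.8%, 67.8% and 99.0%. In TPM, Gas5 was at 9.47% without library 3, A230103J11Rik at 7.11% without library 4 and Rny3 at 10.2% without library 2.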

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

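Of 53 rows and groups tested for a library far from the rest of the 4, 5 stood out in TPM, where chance alone gives about 1 in 20. That rate assumes normally distributed values, and the items tested overlap. Mir9-3 is a member of the neural group and supplied most of its sum in library 3, so their flags are not separate. In library 3, Mir9-3 was at 2861 TPM against 345 in the next highest library, the neural group at 3367 against 601, the miR-106a/miR-363 cluster at 408 against 77.2 and the miR-200 family at 86.8 against 39.0 TPM. In library 4 the miR-23/miR-27/miR-24 group was at 41.9 TPM, against 342 in the library nearest to it. As shares of the miRNA total, a scale chosen after the values had been seen, only Mir9-3 passed the critical value, with a ratio of gap to range of 0.834, and the neural group was just below it at 0.823. The shares in libraries 1 to 4 were 0.0427%, 0.118%, 0.661% and 0.432% for miR-106a/miR-363, 0.0917%, 0.0553%, 0.141% and 0.191% for miR-200, highest in library 4, and 0.805%, 0.556%, 0.634% and 0.255% for miR-23/miR-27/miR-24, with ratios of 0.371, 0.372 and 0.546. The tests below on GC content, on exons of other genes and on neighbouring miRNAs were set before their results were seen. Those on overlapping rows, gene copies, sampling, the miRNA share and library 3 were chosen after the values had been seen, and the bound for a general excess of other tissues was made stricter then, with no change in its reading; that for overlapping rows was made stricter too, which left it open.

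The high neural level of library 3 was examined first. Read-counting noise is argued against for Mir9-3. The lower 95% Poisson bound of its share of miRNA reads in library 3 was 5.436 times the upper bound of the next library. These bounds cover counting error only, and every pair of libraries differed beyond such error. A general excess of other tissues is argued against as well, because the endothelial, striated muscle, liver and both epithelial groups, rescaled to the miRNA total, had a median log2 ratio of -0.03246 in library 3 to the other libraries (SD 0.907), against 2.21 for the neural sum; in TPM the median was 0.75 (SD 0.905) against 2.99, with 3 of the 5 groups highest in library 3, so on that scale such an excess falls short of the neural rise but is not ruled out as a part of it. Neural cells among the sorted cells remain a candidate explanation: after rescaling to the miRNA total, 4 of 6 neural members were highest in library 3 (5 of 6 in TPM, and 3 of 6 were detected in every library) and their median log2 ratio was 1.242 (SD 2.13), with miR-9 at 4.05, miR-219a at 4.29 and miR-124 at 2.16, but miR-128 at -0.67. A gate on tdTomato would remove neural cells that never expressed Tbx18, miR-128 and miR-138 (0.02) did not follow, and no biological difference between the libraries was tested, since the labels give no group for it.

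Library 1 had the highest let-7 and the lowest miR-302 level, a pattern noticed in the same data. Hairpin GC content is argued against. The let-7 median log2 ratio of library 1 to the others was 3.02 before and 3.049 after a loess correction on GC. That of miR-302 moved from -2.20 to -2.08. The GC used was that of the whole hairpin, so the GC of the mature arm was not tested. Read-counting noise is argued against for let-7 too. Let-7 took 10.49% of miRNA reads in library 1 and 2.81% in library 4, the next highest. The lower Poisson bound of the former was 3.598 times the upper bound of the latter. These bounds cover counting error only, and every pair of libraries differed beyond such error. The miR-302 group, with 19 reads in library 1, was not put to this test. A different miRNA share of the TPM total is also argued against, since let-7 in library 1 was 3.731 times the next library after rescaling to the miRNA total. A difference in embryo stage or cell mix between libraries stays open, since the labels give no group for it and no biological explanation was tested.

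Mir214, Mir199a-2, Mir21a, Mir322 and Mir503 were listed at 0 in all libraries. Sharing of reads with an identical copy is argued against for them as a set, since 1 of the 5, Mir199a-2, has a numbered copy. For Mir199a-2 itself such sharing stays open, because 100% of the miR-199a level was listed under Mir199a-1. Reads on overlapping rows may have been left uncounted. Of the miRNA genes that overlap another miRNA row, 92.86% (13 of 14) were at 0, the exception being Mir374b at 3.07 TPM. Of 562 that overlap no row, 28.3% were at 0 (Fisher's exact p = 1.12e-06). The 14 overlap each other in pairs, such as Mir24-1 with Mir3074-1. They are thus not independent, and this p-value overstates the evidence. None of the 5 named genes overlaps another miRNA row. Of the 5, 4 overlap a non-miRNA row, a class in which 41.9% of the others were at 0. These were 26 of 62 (Fisher's exact p = 0.0286 against genes that overlap no row). Mir21a overlaps no row of this table but lies within Vmp1, a protein-coding gene. The TPM scaling included genes outside this table, so an overlap with such a gene could not be tested for Mir21a. Loss of reads on overlapping genes therefore stays open for all 5. The other two explanations cannot be told apart from it: among other miRNA genes the odds ratio of a 0 inside an exon of another gene was 1.852 (40.8% of 184 against 27.1% of 454, Fisher's exact p = 0.000928), above 1 but below the bound of 2 set beforehand, and 3 of the 5 lie in such an exon. For Mir322 and Mir503 alone, lack of transcription was set against their neighbours' median of 11.62 TPM (SD 7.63). That median lies within its spread of the bound of 10, so lack of transcription stays open. Among these neighbours, Mir351 was itself listed at 0 and overlaps another row, which lowers the median. The others, miR-450a at 23.3 ± 12.3, Mir450b at 13.8 ± 8.20 and Mir542 at 9.39 ± 7.26 TPM (SD, n = 4), were detected in all 4 libraries.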

How the results depend on the processing

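No paired analysis was possible because there is 1 group. The arm comparison and the alternatives built on arms could not be run, since rows are precursor genes. The alternatives on recovered reads, on gene copies, on rescaling to the miRNA total, on miRNA genes alone, on ranks within each library, on members at 0 and on the locus of Mir92-2 and Mir19b-2 were chosen after seeing the data. Among alternative values of the 16 group ratios, 122 kept their sign and 8 did not; since no ratio can pass 0.05 by the exact sign-flip test with 4 libraries, a kept sign says nothing about significance by that test. With Mir92-2 and Mir19b-2 counted in the miR-106a/miR-363 group, the ratio of miR-17/miR-92 to miR-106b/miR-25 was -0.72 and to miR-106a/miR-363 -0.77, since Mir92-2 holds most of the miR-17/miR-92 sum. With the median over members, the ratio of miR-199/miR-214 to miR-143/miR-145 was -0.27, to endothelial Mir126a -1.99 and to the neural group 3.78, and that of miR-17/miR-92 to miR-106b/miR-25 was -0.44; a median over 3 members of which Mir214 is at 0 weighs that 0 fully. The neural ratio was 0.50 without library 3 and 0.18 without library 4, from a range of -0.62 to 0.50. Detected miRNAs fell from 213 to 113 at 10 TPM or more in all libraries, by the construction of a stricter limit, and rose to 238 without library 4. Over all rows above 0, the median Pearson's r was 0.960 and Spearman's rho 0.561, as many rows near 0 enter. The groups at or above the 97.5th percentile fell from 9 to 4 against a background of at least 1 TPM, since the comparison then holds only higher miRNAs, and were 8 without any given library. Called cluster members fell from 34 to 21 of 26 at a mean of at least 10 TPM, and were 30 to 34 when a library was left out. Of 25 earlier calls still tested at 10 TPM, 4 were lost (Mir17, Mir19a, Mir20a and Mir450-1) and 3 changed sign: Mir20b, called at -0.66 after 0.72, and, not called, Mir19a and Mir20a. Dropping low members raises a group's mean. With a pseudocount of 10, 28 were called, and Mir19a, Mir20a, Mir20b, Mir302d, Mir467d and Mir669a-12 were lost. Mir93 was lost without library 1, Mir221, Mir222, Mir467d and Mir93 without library 2, Mir19a and Mir467d without library 3, and Mir19a without library 4 and with the sum of gene copies. With members of any mean above 0, Mir302c and Mir367 joined the miR-302/miR-367 group and lowered its mean, so Mir302d turned to 0.18, and Mir467d and Mir669a-12 lost their calls. Library 4, with 146255 miRNA reads, limits what can be seen of low miRNAs.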

Other observations

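The let-7 genes of 3 loci share a locus with a miR-99 or miR-100 gene, and their ratio to that neighbour differed between libraries. Mirlet7c-1 over Mir99a was 0.433, 0.109, 0.0653 and 0.321 in libraries 1 to 4. Mirlet7a-2 over Mir100 was 1.13, 0.242, 0.0673 and 0.550, and Mirlet7e over Mir99b was 0.144, 0.0676, 0.0438 and 0.131. At all 3 loci library 1 was highest, library 4 next, then library 2, and library 3 lowest. These pairs were chosen after the let-7 levels had been seen, and no explanation was tested.

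Some abundant miRNAs lay outside the fixed groups, and they are named here after their values were seen. Mir218 summed to 623 TPM over its copies and Mir7 to 464 TPM. Mir335, at 803 ± 463 TPM (SD, n = 4), lies in an intron of Mest, an imprinted gene, on chromosome 6 at 30741299 to 30741396. Y RNA genes summed to 1425 ± 407 TPM and guide RNA genes to 276 ± 91.0 TPM (SD, n = 4). Rny1 was highest in library 4, at 1588 TPM, the library in which miRNA genes made up the smallest share of the table, 70.3%.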
